A study of Danio rerio with 12 samples.

How the data were processed

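RNA was measured in 12 libraries from zebrafish of the EK strain at 5 days post-fertilisation. Each library came from a pool of 5 whole embryos, offspring of fish fed diets with 0, 1, 3 or 10 ppm methylmercury (MeHg) through their life cycle, with 3 pools for each diet. The labels do not say whether the pools of a diet came from separate clutches or parents, so p-values measure the spread between these pools. Per the labels, libraries were made with a TruSeq kit and read as paired ends of 100 base pairs, with 12 samples in a lane. Per the submitters' processing notes, CASAVA 1.8.2, cutadapt, FastQC, TopHat and Cuffnorm were used with the genome build Zv9. Their roles, settings and the gene annotation release are not given in the sources used here.

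The deposited count table held fragment counts per gene that the authors had divided by 1 size factor per library, so its values were a scaled signal and not raw counts. This was read from the values: between 98.1% and 98.6% of the values above 0 in a library were whole multiples of 1 step, within a tolerance of 0.02 steps, and the steps lay between 0.564 and 1.17. Dividing by these steps gave 5.63 to 11.8 M (mega) fragments per library, which sets the precision, while the deposited totals lay between 6.17 and 6.74 M. The deposited FPKM table held fragment values scaled by transcript length and library total, as computed by the authors. Symbols came from the deposited tables for 20495 of 32674 genes and from a gene names table for 1553 others; 10626 rows had none. No genome of the build used by the authors was at hand, so no coordinates are given, and neighbourhood was taken from the RefSeq gene order of another assembly (GRCz12tu).

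The tests were fixed before the data were examined, with 1 version for raw counts and 1 for scaled values. The table proved to be scaled, so the version for scaled values was used. limma 3.58.1 in R 4.3.3 was fitted to log2(value + 1) of the 18390 genes with a mean of at least 10 over the 12 libraries, with a mean-variance trend, robust moderation and all 12 libraries in 1 fit. Fold changes are on that log2(value + 1) scale, which understates the change of low genes. Each dose was compared with control and with each other dose. An F-test covered any difference among the 4 diets, and a trend was fitted on the ranks of the diets. Tests were two-sided, with Benjamini-Hochberg adjustment at 0.05. The 43 gene lists were fixed in advance and tested with limma's camera at a correlation of 0.01, adjusted over lists and the 3 contrasts with control, and again with an estimated correlation and with fry.

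Genes named in the text followed a rule fixed in advance: the largest changes that passed at each dose, or, where fewer than 5 passed, the 10 smallest p with a symbol; up to 4 members of each list that passed; fixed background markers; and the 12 smallest p of the F-test and of the trend. Markers gstp1 and cyp1a had no row under those symbols, and hsp70l lay under the minimum mean. On simulated data with 100 genes changed 2-fold and 100 changed 4-fold among 18390, the fit recovered 52, 56 and 61 of the 2-fold genes and 91, 87 and 93 of the 4-fold genes at 1, 3 and 10 ppm, with 7, 6 and 10 false calls. Genes of the synapse list were also shifted and were left out of the false calls. The simulated noise was independent between genes, unlike that of the real libraries, so these rates do not describe recovery or false calls in the real data.

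A clock score was computed after the data were seen, as the first principal component of the 46 tested members of the fixed clock list, signed so that per1b was high. Alternatives fixed in advance were another rescaling, other filters, pseudocounts of 5 on the scaled counts and of 0.1 and 1 on FPKM, limma-voom, the replicate number as a block, fits on the libraries of the compared groups only, other dose scales, and leaving out each library. Alternatives chosen after seeing the data were the clock score as a covariate, leaving out the 4 libraries of high clock score (which leaves 1 control and 1 library of 1 ppm, each assumed to vary like the 3 ppm and 10 ppm libraries that give the spread), limma-voom on recovered fragments, library weights, and leaving out 3 myosin genes. Python 3.11.15 with pandas 2.3.3 prepared the tables and matplotlib 3.10.9 drew the figures.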

Results

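Gene expression was measured in 5-day-old zebrafish whose parents had eaten diets with 0 (control), 1, 3 or 10 ppm MeHg, an organic mercury compound that accumulates in fish and affects the nervous system. Each diet had 3 libraries. The depth recovered from the deposited values was 7.04, 9.62 and 7.42 M (mega) fragments in control libraries 1 to 3, 7.44, 7.30 and 5.63 M at 1 ppm, 8.78, 9.62 and 11.4 M at 3 ppm, and 8.07, 8.02 and 11.8 M at 10 ppm. Between 18970 and 20071 genes reached 1 FPKM in a library. Correlations between libraries over the tested genes lay between 0.926 and 0.980, with a median of 0.970 within diets and 0.965 between them.

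Clock genes differed between libraries of the same diet. The transcriptional repressor gene per1b had scaled counts of 78.2, 864 and 721 in control libraries 1 to 3 and of 57.0, 549 and 550 in the 1 ppm libraries, against 49.4 to 78.6 at 3 ppm and 52.1 to 54.1 at 10 ppm. The nuclear receptor gene nr1d1 followed the same order, with 14.9, 1694 and 967 in the controls and 13.6, 394 and 571 at 1 ppm. The receptor gene rorcb went the other way, with 237, 17.5 and 8.96 in the controls and 154, 39.7 and 3.51 at 1 ppm. The first principal component of the clock list held 88.3% of its variance, and its score was positive in 4 libraries, control 2 and 3 and 1 ppm 2 and 3. It was negative in the other 8, which include all 6 libraries of 3 and 10 ppm, so clock state and diet were partly confounded. The split was not limited to the clock list. The first principal component of all tested genes held 34.3% of their variance. Its score was positive in the same 4 libraries (25.4, 37.2, 12.6 and 65.6) and negative in the other 8. As a set the 46 tested clock genes did not pass camera at 1, 3 or 10 ppm (adjusted p = 0.0721, 0.455 and 0.702). That test looks for a shift in 1 direction, and this list holds genes that move in opposite directions. It therefore cannot tell whether the clock genes changed. Over all genes 0 of them passed with limma, and adjusted over the list alone 0, 15 and 20 passed, among them bhlhe40 and per3 at 3 and 10 ppm.

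**Figure D1:**
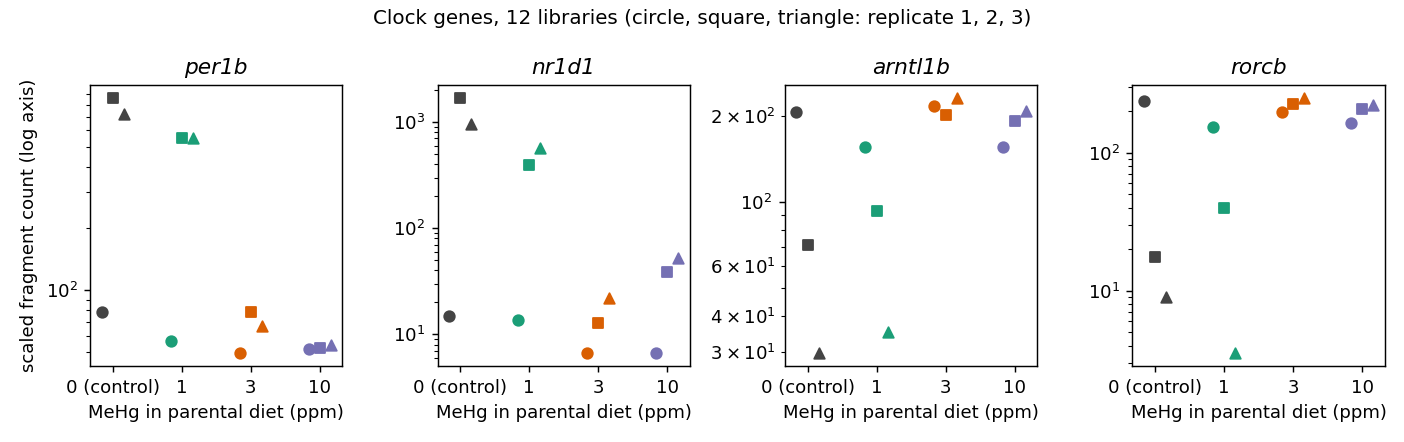
Scaled fragment counts of 4 clock genes (log axis) in each of the 12 libraries, by ppm of MeHg in the parental diet. For per1b, replicates 2 and 3 of control and of 1 ppm lie between 549 and 864, and every other library lies at 78.6 or below.

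At 1 ppm against control, the question was whether the lowest diet left a change in the offspring, and no single gene passed. The nearest was nupr1, a stress-induced chromatin regulator, with 811 ± 41.0 scaled counts at 1 ppm and 456 ± 97.2 in controls (SD, n = 3; log2 fold change 0.85, SE 0.15; limma adjusted p = 0.810). The other genes of smallest p did not pass either: log2 fold changes were 1.33 for dedd1, 1.06 for the oxidase gene duox, 1.31 for ddx43, 0.93 for the natriuretic peptide receptor gene npr1a, 0.68 for the integrin gene itga10 and 1.24 for akip1. They were -0.70 for otx5, a photoreceptor and pineal transcription factor gene, -0.86 for impact and -1.36 for MDGA1. With limma, 0 of 18390 genes passed, 361 had an unadjusted p under 0.05, where chance gives 920, and limma-voom called 0.

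As sets, 7 of the 43 lists passed at 1 ppm with camera. Hepatocyte genes fell (52 of 62 members lower, median log2 fold change -0.25, adjusted p = 2.70e-07), among them cp (ceruloplasmin; -0.52) and tdo2a (-0.36), which did not pass singly. Phototransduction genes fell (50 of 59 lower, median -0.25, adjusted p = 4.14e-07), as did lens crystallins (45 of 53, median -0.24, adjusted p = 0.000992), glucocorticoid and stress axis genes (23 of 28, median -0.24, adjusted p = 0.00232) and ribosomal protein genes (66 of 72, median -0.06, adjusted p = 0.0127). DNA replication genes rose (59 of 63 higher, median 0.20, adjusted p = 1.75e-05), as did exocrine pancreas enzymes (21 of 22, median 0.33, adjusted p = 0.00207). Every one of these calls was lost with an estimated correlation (adjusted p = 0.964). Over all genes and adjusted over the list alone, 0 members of these lists passed with limma. The pancreas list turned direction without control replicate 3 (median -0.10) and its call ended without 1 ppm replicate 1 (0.18) or 2 (0.02). The lens call ended without control replicate 1 (-0.06) or 2 (-0.23) or 1 ppm replicate 1 (-0.11), and the DNA replication call without 1 ppm replicate 3 (0.09). The glucocorticoid call ended without control replicate 2 (-0.09), and the ribosomal call with the clock score as a covariate (adjusted p = 0.0502), with FPKM (median -0.04) and without control replicate 2 (-0.04) or 3 (-0.06) or 1 ppm replicate 1 (-0.06) or 3 (-0.03). Other medians moved by over 1.5 times while the call held. Without 1 ppm replicate 3 they were -0.10 for hepatocyte, -0.15 for phototransduction and 0.75 for pancreas genes. Without control replicate 3 they were -0.45 for lens and -0.41 for glucocorticoid genes, without control replicate 2 0.65 for pancreas genes, and without 1 ppm replicate 2 0.32 for DNA replication and -0.11 for ribosomal protein genes.

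At 3 ppm against control, 3 neighbouring genes of fast muscle myosin heavy chains, the motor proteins of muscle fibres, were listed at 0 in all 3 libraries. The gene myhz2 (ENSDARG00000012944) had scaled counts of 22300, 25600 and 29560 in controls, myhc4 (ENSDARG00000035438) had 1992, 1671 and 1715, and myha (ENSDARG00000095930) had 203, 166 and 140. Those at 1 ppm and 10 ppm lay between 14830 and 35540 for myhz2, 1065 and 2252 for myhc4, and 50.7 and 284 for myha. The FPKM table also listed them at 0 at 3 ppm. These 3 genes were the only ones to pass (limma adjusted p = 8.69e-13, 1.32e-11 and 1.19e-05); no fold is given against a group listed at 0. The 74 tested muscle contractile genes did not pass as a set (38 higher, 36 lower, median 0.02, camera adjusted p = 0.455), and the median and the test differed in sign. With limma-voom 2 genes passed, and myha did not, nor did it with FPKM and 1 added. Values of near-identical myosin copies depend on how fragments were shared between them.

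**Figure D2:**
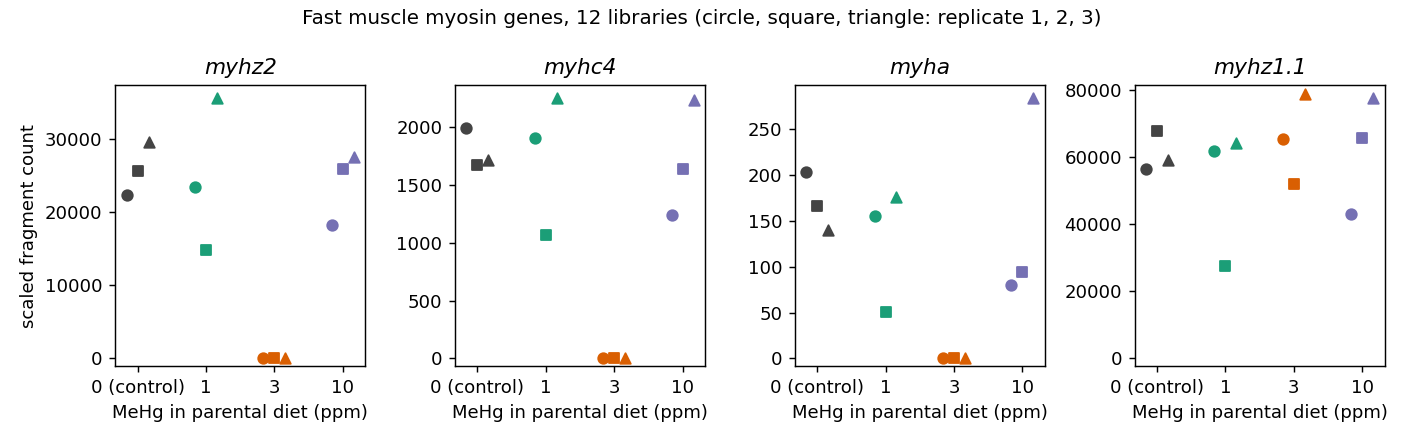
Scaled fragment counts of 4 fast muscle myosin genes in each of the 12 libraries, by ppm of MeHg in the parental diet. The genes myhz2, myhc4 and myha sit at 0 in the 3 libraries of 3 ppm, while their neighbour myhz1.1 lies at 52060 to 78890 there.

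Other genes of smallest p at 3 ppm did not pass. The synaptotagmin gene syt13 had 161 ± 20.3 scaled counts against 310.5 ± 37.2 in controls (SD, n = 3; log2 fold change -0.95, SE 0.16; limma adjusted p = 0.170). The chaperone gene hspa4l had 121 ± 4.85 against 245 ± 22 (adjusted p = 0.189) and inhbb, an activin and inhibin subunit gene, 229 ± 62.8 against 108 ± 20.9 (adjusted p = 0.323). Log2 fold changes were -0.84 for sh3gl2, which acts in synaptic vesicle endocytosis, -0.88 for arhgef9b, -0.82 for the aldolase gene aldocb and -2.32 for prkacbb, a protein kinase A subunit gene. In all, 1912 genes had an unadjusted p under 0.05, where chance gives 920. Genes vary together, so such counts, here and at the other doses, can stray far from that number without an effect of diet. Clock state also differed between the 3 ppm libraries and most controls. Without control replicate 1, the control library of low clock score, 17 genes passed, with library weights 238 and with the clock score as a covariate 6.

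Of the 43 lists, 8 passed at 3 ppm with camera. Genes of oxidative phosphorylation fell, both the nuclear-encoded (78 of 84 lower, median -0.28, adjusted p = 4.85e-10) and the mitochondrially encoded (13 of 13, median -0.38, adjusted p = 7.25e-07). Of the latter, 9 passed adjusted over the list alone and 0 over all genes, for example mt-nd3 (2106 ± 194 against 3194 ± 583; SD, n = 3). Synapse genes fell (57 of 74, median -0.20, adjusted p = 1.02e-05), with 9 passing over the list alone, among them the GABA synthesis and transport genes gad1b (-0.74) and slc32a1 (-0.71). Genes of neuronal differentiation fell as a set (38 of 52, median -0.16, adjusted p = 0.000778), and 0 members passed with limma over all genes or adjusted over the list alone; stmn1b had -0.61 (adjusted p = 0.382). Heat shock genes fell (27 of 36, median -0.34, adjusted p = 8.94e-05), with hspa4l passing over the list alone, and so did ribosomal protein genes (65 of 72, median -0.11, adjusted p = 0.00145). Hepatocyte genes rose (48 of 62 higher, median 0.23, adjusted p = 0.00145), as did cartilage and skeletal matrix genes (43 of 57, median 0.17, adjusted p = 0.00580), of which kera (0.74), a proteoglycan gene of the cornea, passed over the list alone. With an estimated correlation every call at 3 ppm was lost (adjusted p = 0.964). With the clock score as a covariate, the calls of heat shock, hepatocyte and nuclear-encoded oxidative phosphorylation genes ended. Their medians were 0.03, -0.06 and -0.08. The call of ribosomal protein genes also ended there (camera adjusted p = 0.199) and with FPKM (median -0.03). The synapse call held with a median of -0.39 (camera adjusted p = 2.35e-11), as did the mitochondrially encoded, neuronal differentiation and cartilage calls. This cannot separate diet from clock state, because control replicate 1 was the only control to share the low clock score of the 3 ppm libraries. That library had a synapse list median of 0.28, against 0.10 and -0.09 in control replicates 2 and 3. Without control replicate 1 the calls of synapse (median -0.07), neuronal differentiation (-0.15) and cartilage genes (0.09) ended. The cartilage call also ended without 3 ppm replicate 1 (0.02), and the hepatocyte call without control replicate 2 (0.16). Calls held but medians moved by over 1.5 times for heat shock genes without control replicate 3 (-0.20) or 3 ppm replicate 3 (-0.22) and for hepatocyte genes without control replicate 1 (0.35) or 3 ppm replicate 1 (0.14).

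**Figure D3:**
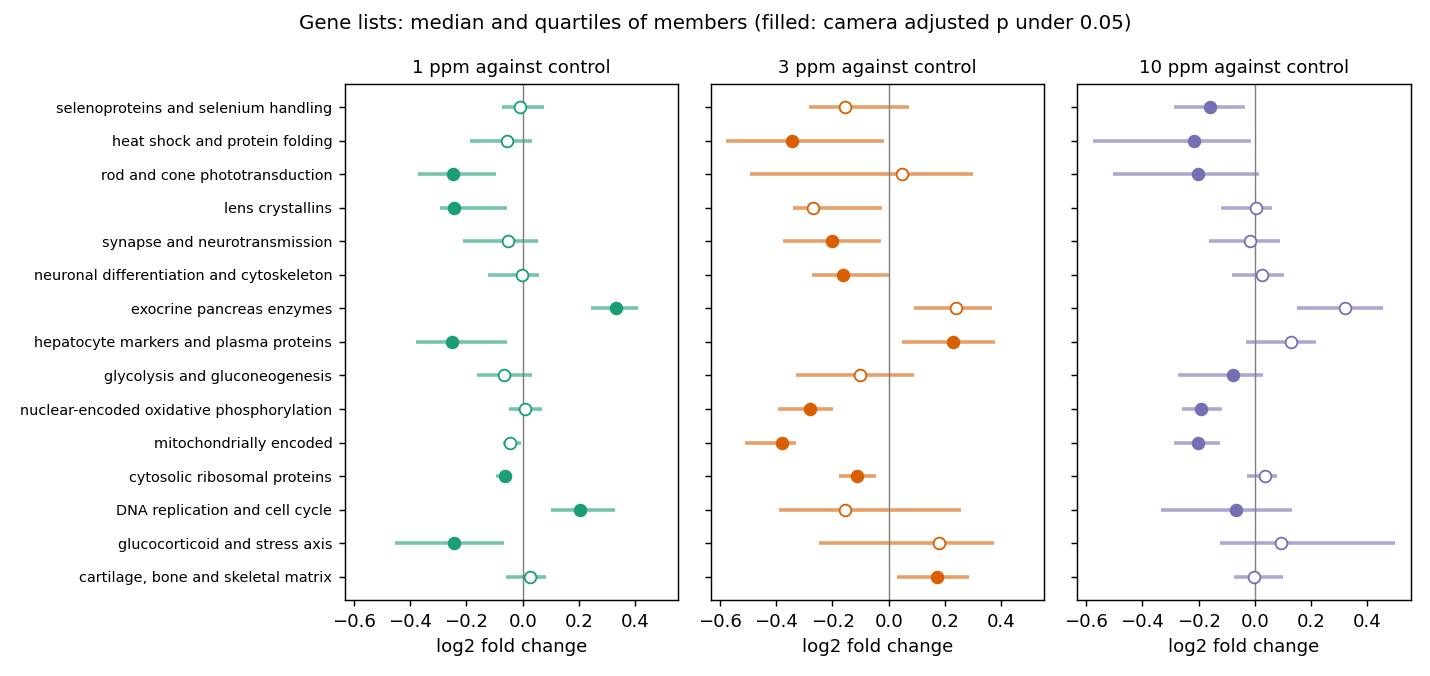
Median (points) and quartiles (bars) of the log2 fold changes of list members against control at 1, 3 and 10 ppm, for the 15 lists that passed at any dose. Filled points passed camera at a correlation of 0.01; mitochondrially encoded genes at 3 ppm have the lowest called median, -0.38.

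At 10 ppm against control no single gene passed. Of the genes of smallest p, slc1a2a, a glutamate transporter gene, had 28.6 ± 5.38 scaled counts against 89.6 ± 20.6 in controls (SD, n = 3; log2 fold change -1.61, SE 0.25; limma adjusted p = 0.202), and gabrr1, a GABA receptor subunit gene, 10.5 ± 1.93 against 59.7 ± 22.5 (adjusted p = 0.202). Log2 fold changes were -0.73 for pdcb, a phosducin gene, -1.38 for bhlhe40, a repressor gene of the clock list, -1.14 for lactbl1a, -1.04 for the retinal homeobox gene rx1 and -1.53 for the cone opsin kinase gene grk7a. They were 1.27 for inhbb, 0.85 for kera and 0.89 for the RNA-binding protein gene fus. With limma, 0 of 18390 genes passed, 1050 had an unadjusted p under 0.05 where chance gives 920, and limma-voom called 0. Without control replicate 1, the control library of low clock score, 41 genes passed, with library weights 38 and with FPKM 1, kera. That omission left only controls of high clock score against 10 ppm libraries of low clock score.

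At this dose 7 of the 43 lists passed with camera, and each fell. Phototransduction genes had 43 of 59 members lower (median -0.20, adjusted p = 2.67e-05), and 9 lower and 1 higher member passed adjusted over the list alone, among them the cone arrestin gene arr3a (-1.69) and irbp (-0.87). Oxidative phosphorylation genes fell, nuclear-encoded (79 of 84, median -0.19, adjusted p = 2.38e-07) and mitochondrially encoded (13 of 13, median -0.20, adjusted p = 0.00306). Heat shock genes (27 of 36, median -0.22, adjusted p = 0.000992), selenoprotein genes (23 of 30, median -0.16, adjusted p = 0.00744), glycolysis genes (26 of 43, median -0.08, adjusted p = 0.0187) and DNA replication genes (36 of 63, median -0.07, adjusted p = 0.0389) fell as well. Over all genes 0 members of these lists passed with limma. Adjusted over the list alone, 0 selenoprotein genes passed, and the iodothyronine deiodinase gene dio1 had -0.78 (adjusted p = 0.774). With an estimated correlation every call at 10 ppm was lost (adjusted p = 0.964). With the clock score as a covariate only the phototransduction call of these 7 held (median -0.34, adjusted p = 2.40e-09), 14 lists passed, 11 higher and 3 lower, and the medians of nuclear-encoded oxidative phosphorylation and heat shock genes were 0.02 and 0.07. Calls ended for selenoprotein genes without 10 ppm replicate 2 (-0.06) and for heat shock genes without control replicate 3 (-0.08). The glycolysis call ended without control replicate 1 (-0.11) or 2 (-0.05) or 10 ppm replicate 1 (-0.05) or 2 (-0.05), and that of mitochondrially encoded genes without control replicate 1 (-0.18) or 3 (-0.14) or 10 ppm replicate 2 (-0.08). The DNA replication call ended without control replicate 1 (-0.21) or 3 (-0.03) or 10 ppm replicate 1 (-0.15) or 2 (0.05) or with the replicate number as a block (-0.07). Calls held but medians moved by over 1.5 times for nuclear-encoded oxidative phosphorylation genes without control replicate 1 (-0.30) or 3 (-0.11) or 10 ppm replicate 2 (-0.07). The same held for phototransduction (-0.12) and heat shock genes (-0.37) without control replicate 1, for selenoprotein genes without control replicate 3 (-0.08), for glycolysis genes without 10 ppm replicate 3 (-0.16), and for DNA replication genes without control replicate 2 (-0.16) or 10 ppm replicate 3 (-0.21).

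Background markers of metal and oxidative response did not pass at any dose. The metallothionein gene mt2, a metal-binding protein gene, had 379 ± 70.8 scaled counts in controls, 307 ± 81.9 at 1 ppm, 217 ± 33.3 at 3 ppm and 208 ± 46.4 at 10 ppm (SD, n = 3; limma adjusted p = 1.00, 0.382 and 0.525 against control); adjusted over the 14-member metal list alone it passed at 3 and 10 ppm. The metal list (adjusted p = 0.813, 0.604 and 0.813) and the Nrf2 and glutathione list (0.420, 0.244 and 0.299) did not pass camera at 1, 3 and 10 ppm. Log2 fold changes at 1, 3 and 10 ppm were 0.56, 0.19 and -0.61 for gpx1a, 0.24, 0.08 and -0.03 for gpx1b, -0.35, 0.63 and 0.48 for hmox1a, and 0.07, 0.25 and 0.05 for sepp1a. Tissue markers also did not pass, with values of -0.24, 0.04 and 0.16 for fabp10a (liver), -0.19, 0.36 and -0.32 for rho (rods), -0.12, 0.05 and -0.10 for opn1sw1 (ultraviolet cones) and -0.12, -0.10 and 0.06 for mbpa (myelin). The glucocorticoid target gene fkbp5 ranged from 69.9 to 1283 within the controls, and its log2 fold changes were -1.83, 0.67 and 1.63.

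A trend over the 4 diets passed for 4 genes, each lower at higher dose (limma adjusted p = 0.0426 for each). The slope per diet step was -0.81 (SE 0.12) for gabrr1, -0.51 (SE 0.08) for slc1a2a, -0.26 (SE 0.04) for pdcb and -0.50 (SE 0.08) for bhlhe40 on the log2 scale. Scaled counts of pdcb went from 885 ± 48.3 in controls to 767 ± 64.4, 590 ± 35.7 and 536 ± 80.9 at 1, 3 and 10 ppm, and those of bhlhe40 from 1624 ± 597 to 1401 ± 270, 757 ± 64.3 and 596 ± 75.2 (SD, n = 3). Slopes of genes that did not pass were -0.38 for lactbl1a, 0.50 for inhbb, -0.53 for grk7a, 0.33 for kera, 0.30 for fus, -0.36 for rx1 and -0.50 for ncaldb. None of the 4 genes passed with the clock score as a covariate (adjusted p = 1.00), where the slopes were -0.54, -0.44, -0.20 and -0.27. The gene bhlhe40 is itself part of the clock score, so its slope with that covariate is not an independent check. None of the 4 genes passed with dose in ppm or log2(ppm + 1), with FPKM or without a filter. Nor did any with a minimum mean of 50, under which gabrr1 was not tested. With the replicate number as a block gabrr1 passed and the other 3 did not. Without control replicate 1, the control library of low clock score, 146 genes passed, without 1 ppm replicate 2 or 3 there was 1, and without any 1 of the other 9 libraries 0.

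**Figure D4:**
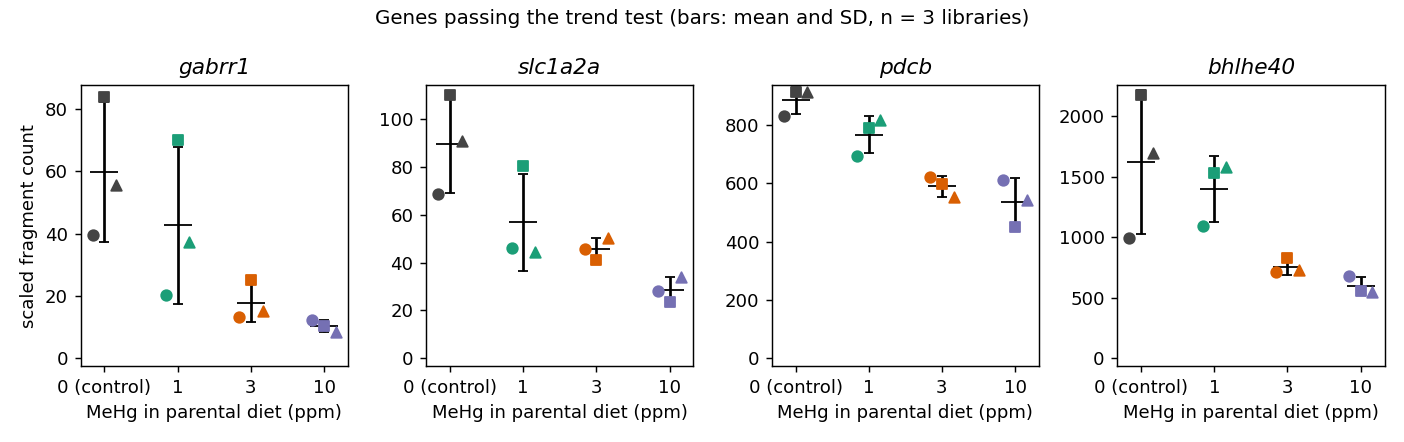
Scaled fragment counts of the 4 genes that passed the trend test in each of the 12 libraries, by ppm of MeHg in the parental diet; horizontal marks and bars are mean and SD (n = 3). Control means are 59.7, 89.6, 885 and 1624 for gabrr1, slc1a2a, pdcb and bhlhe40, and those at 10 ppm are 10.5, 28.6, 536 and 596.

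The F-test over the 4 diets passed for myhz2, myhc4 and myha (limma adjusted p = 9.54e-13, 1.44e-11 and 2.25e-05) and for no other gene. The next was inhbb (adjusted p = 0.0581), followed by mhc1zca, a class I histocompatibility gene, with 39.8 ± 1.82 scaled counts in controls, 23.3 ± 7.81 at 1 ppm, 53.1 ± 13.3 at 3 ppm and 81.9 ± 8.53 at 10 ppm (SD, n = 3; adjusted p = 0.203). Between doses, the same 3 myosin genes were lower at 3 ppm than at 1 ppm and higher at 10 ppm than at 3 ppm. Between 10 and 1 ppm 0 genes passed with limma, 1486 had an unadjusted p under 0.05, and limma-voom called 0.

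Between doses, 10 of the 43 lists passed camera for 3 against 1 ppm (4 higher, 6 lower), 13 for 10 against 1 ppm (7 higher, 6 lower) and 10 for 10 against 3 ppm (6 higher, 4 lower). The smallest p were those of hepatocyte genes at 3 against 1 ppm (median 0.45, adjusted p = 2.07e-09), DNA replication genes at 10 against 1 ppm (median -0.37, adjusted p = 1.09e-07) and ribosomal protein genes at 10 against 3 ppm (median 0.14, adjusted p = 6.63e-07). Phototransduction genes were lower at 10 than at 3 ppm (median -0.15, adjusted p = 0.000323) and did not pass between 10 and 1 ppm (median 0.03, adjusted p = 0.787). No list differed between doses with an estimated correlation (adjusted p = 0.958 at the lowest).

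In the fit reported here, no gene was called against control at more than 1 dose. With FPKM kera was called at both 3 and 10 ppm, and without control replicate 1 or with library weights bhlhe40 and ncaldb, among others, were. Log2 fold changes over all tested genes correlated across genes, which are not independent replicates, at 0.152 between 1 and 3 ppm, 0.211 between 1 and 10 ppm and 0.648 between 3 and 10 ppm. In 100 simulated draws of unchanged groups against shared controls, the median correlation was 0.567, with 95% of draws between -0.321 and 0.892. The covariances were 0.0147, 0.0173 and 0.0798, against a simulated median of 0.0358 (-0.0135 to 0.141), so each lay within the range that shared controls give. With 3 controls they could not be split into parts of at least 2.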

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

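The 3 tests on the myosin genes and the tests of the clock arms and of an exchange of libraries were chosen after the values they use had been seen. The test of the tissue mix was written before, but it was run in a form stricter than 1 reading of its rule. Its resampling of genes was added after. The myosin genes differed between doses by the test of that difference itself. At 3 ppm against 1 ppm, limma adjusted p was 9.93e-13 for myhz2, 1.50e-11 for myhc4 and 3.14e-05 for myha; at 10 ppm against 3 ppm it was 9.74e-13, 1.51e-11 and 2.19e-05.

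All 9 values of these genes at 3 ppm were exactly 0, and 0 other protein-coding genes lay between them in the RefSeq order (GRCz12tu), so a failed estimate at one locus in the authors' processing stays a candidate explanation; these zeros prompted it and add no support. Less fast muscle tissue is argued against, because the other 66 tested muscle genes outside the myosin heavy chains had a median log2 fold change of 0.0238 (95% bootstrap interval over genes -0.05 to 0.08; 95% interval of the difference over library medians -0.43 to 0.53), where the explanation needs -1 or below. Fragments given to near-identical neighbouring copies stay open: relative to those muscle genes, the sum of myhz1.1, myhz1.2 and myhz1.3 was 0.12 higher at 3 ppm on the log2 scale (95% interval -0.26 to 0.51), where 0.35 would hold the missing fragments. An effect of the diet on this locus is not excluded.

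Clock genes set 4 libraries of control and 1 ppm apart, and in 6 of the 6 control and 1 ppm libraries, the medians of the per and nr1d arm and of the arntl, clock and ror arm (16 genes) deviated from their diet's mean in opposite directions. That was visible in the values that prompted the test, so libraries collected at different times of day or light stay open as a candidate explanation. A different mix of tissues in those pools stays open. Of the 14 tissue lists, 0 ranged over at least 0.5 of the range of the clock arm in its order in both diets (at most 0.05% of resamples of a list's genes did). The rule fixed in advance can also be read as asking for that range in either diet, with the same library order in both. Exocrine pancreas genes met that reading, at 0.481 and 0.582 in control and 1 ppm, though not in the clock's order. Pigment epithelium genes followed the clock's order at 0.205 and 0.189. An exchange of these libraries with 3 ppm or 10 ppm libraries stays open, since 0 of those 6 had a high clock score, which an exchange allows. No biological explanation was tested, since diet does not vary within these groups.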

How the results depend on the processing

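The clock covariate, the libraries of low clock score, the library weights and the fits without the myosin genes were chosen after seeing the data. The libraries of low clock score hold 1 control and 1 library of 1 ppm, assumed to vary like the others, so their counts cannot separate clock state from these single libraries. The 3 myosin calls at 3 ppm against control, 3 against 1 ppm and 10 against 3 ppm became 0, 0 and 0 when these genes were left out, as did the F-test (0), by construction. Counts at 3 ppm against control were 6 with the clock score as covariate, 7 in libraries of low clock score and 238 with library weights. At 10 ppm against control, 0 genes became 1 with FPKM (0.1 or 1 added, kera) and 38 with library weights. FPKM with 0.1 added gave 6 genes for 3 against 1 ppm, library weights 3 for 10 against 1 ppm, and for 10 against 3 ppm both the libraries of low clock score and the fit on the 2 groups gave 5. The F-test gave 5 with FPKM (0.1 added), 7 in libraries of low clock score and 24 with library weights. The count of 4 trend genes became 0 without a filter, with a mean of at least 50, with the clock score, in libraries of low clock score, with dose in ppm and with log2(ppm + 1), 1 with FPKM (0.1 or 1 added; kera, which rose, and none of the 4) and 101 with library weights, the 4 included. The causes were not tested. In the comparisons with control, the library weights were 0.449 for control replicate 1, of low clock score, and 1.85 and 1.03 for replicates 2 and 3, of high score. These weighted fits, like those without control replicate 1, therefore align clock state more closely with diet.

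With one library left out, counts ranged over 3 to 17 at 3 ppm and 0 to 41 at 10 ppm against control, both highest without control replicate 1. They ranged over 3 to 6 for 3 against 1 ppm and 3 to 5 for 10 against 3 ppm, highest without 3 ppm replicate 1, and 0 to 3 for 10 against 1 ppm, highest without 3 ppm replicate 3 (1 without 3 ppm replicate 1). The F-test gave 7 and 5 without 3 ppm replicate 1 and 3. It ranged over 3 to 9 and the trend over 0 to 146, both highest without control replicate 1; the trend gave 1 without 1 ppm replicate 2 or 3 and 0 without any of the other 9 libraries. At 1 ppm against control 0 genes passed in every alternative run.

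Lists passing at 1, 3 and 10 ppm became 0, 0 and 0 with an estimated correlation and with fry, 14 at 10 ppm with the clock score (11 higher, 3 lower, against 0 and 7), and 14 and 13 at 1 and 10 ppm in libraries of low clock score (8 higher and 6 lower, 9 higher and 4 lower). At 3 ppm, 8 lists (2 higher, 6 lower) became 11 with the clock score (6 higher, 5 lower) and 12 in libraries of low clock score (8 higher, 4 lower), each sharing 4 of the 8. Leaving out libraries gave 6 to 13 lists at 1 ppm and 7 to 14 at 3 ppm. Medians turned for exocrine pancreas at 1 ppm without control replicate 3 (-0.10; without single libraries -0.10 to 0.75) and DNA replication at 10 ppm without 10 ppm replicate 2 (0.0499; -0.213 to 0.0499). With the clock score they turned for heat shock (0.0347) and hepatocyte genes (-0.0645) at 3 ppm and for heat shock (0.0681) and nuclear oxidative phosphorylation (0.0211) at 10 ppm, the last 2 also in libraries of low clock score (0.0261 and 0.0215), where heat shock genes at 3 ppm turned too (0.00630). Of 4496 values of named genes under alternatives, 39 uncalled ones turned sign.

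Over the 4 diets, the replicate number did not pair the libraries: 6 of 18 same-numbered pairs correlated over 0.1 (range -0.227 to 0.472), and 6 of 12 libraries correlated best with their own number. Between control and 1 ppm, however, deviations from the diet means correlated at 0.472 for replicate 1 and 0.442 for replicate 3, against -0.108 for replicate 2. Structure shared by number between these 2 diets is therefore not excluded. With the replicate block the trend gave 1 gene (gabrr1), the F-test 4, the list counts were 8, 8 and 6, and the 6 pairwise gene counts did not move. Depth of 5.63 M fragments in 1 ppm library 3 limits low genes there.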

Other observations

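The test of the lens list was chosen after its values had been seen, and the clock term was added after seeing the data but before its result on this list; the counts of other splits were planned. Exocrine pancreas and glucocorticoid genes varied within diets. The trypsin gene try had 18380, 26340 and 9930 scaled counts in the controls and 22480, 33570 and 10990 at 1 ppm. The glucocorticoid targets fkbp5 and klf9 had 2019 and 1102 in 10 ppm library 2, 2166 and 848 in library 3, and 195 and 246 in library 1.

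Phototransduction genes were lower as a set at 10 ppm. The clock score as a term did not reduce this fall: the median with it was 1.69 times the median without (-0.34 against -0.20), and the list still passed camera (adjusted p = 2.40e-09). This cannot decide on clock phase of the libraries as its whole cause, because only 1 control library shared the low clock score of the 10 ppm libraries. That library, control replicate 1, had a list median of 0.218, against 0.0163 and 0.0617 in control replicates 2 and 3. A smaller share of eye tissue stays open: lens crystallins had a median of 0.00453 where at most -0.10 was needed, but their medians were 0.92, -0.33 and -0.12 in the 10 ppm libraries (95% interval of the difference from control over libraries -1.19 to 1.28), and with the clock term the median was -0.17. Pigment epithelium genes had a median of -0.14, and 0.21 with the clock term. An effect of parental diet on photoreceptor genes may remain as a hypothesis, but the call was lost with an estimated correlation (unadjusted p = 0.0440, adjusted p = 0.964).

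Other splits of the 6 libraries of each pair were counted in fits on those libraries alone, and 10 splits are too few for a share under 0.05. At 1 ppm against control the real split gave 0 genes and the highest other 253, and the latter points to a structure among these libraries other than diet. At 3 ppm against control the real split gave 3 and the highest other 7 (2 splits gave as many), and at 10 ppm 0 and 14. The values were 3 and 0 for 3 against 1 ppm (1 split), 0 and 1 for 10 against 1 ppm, and 5 and 3 for 10 against 3 ppm (1 split). The myosin genes were listed at 0 in every 3 ppm library, so only the real split sets those zeros fully apart. Counts that involve 3 ppm therefore cannot tell an effect of diet from a failed estimate at that locus. Where the real count is 0, all 10 splits give as many by construction, which tests nothing. For lists, the real split gave 7, 10 and 8 at 1, 3 and 10 ppm, and the highest other splits gave 18, 24 and 20, with 10, 9 and 10 splits giving as many.

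Over 100 regroupings of the 12 libraries, the real one included, 8 gave at least the 3 genes of the F-test. The highest other gave 680, so chance cannot be excluded by that count and the libraries hold a structure other than diet. The 3 genes were the myosin genes listed at 0 at 3 ppm, and a count of genes does not bear on how those zeros arose. For the trend, 1 regrouping, the real one, gave as many as 4 genes and the highest other gave 2. Random regroupings thus rarely gave such a count in this setting, the only one in which they were run. Chance is not excluded, because the count is small and became 0 when most single libraries were left out. With dose in ppm, log2(ppm + 1), no filter or a mean of at least 50 the real grouping gave 0 genes, and the count does not separate diet from clock state.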
